A study of Mus musculus with 10 samples.

How the data were processed

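RNA was measured on 10 Agilent one-colour arrays, 1 array per sample, from CD45.2-sorted LSK bone marrow cells of C57BL/6 mice, with 0.02 µg of RNA labelled with Cy3 for each array. The deposited scanner files give an intensity per spot, per the file headers from Feature Extraction 10.7.1.1, whereas the processing notes of the submitters name version 9.1. Per the file headers, that intensity had its local background subtracted and was detrended within the array, with low values replaced by a surrogate. It was not scaled between arrays. The deposited value table holds a ratio: each column was the same intensity averaged per probe and divided by the 75th percentile of the array, which was found by setting each column against each scanner file. No normalization beyond this was found in the values, and the submitters' notes do not state the scaling.

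The columns with gene names and with the mean spot signal were absent from the scanner files. Probes were therefore named through the RefSeq accessions in the files and the RefSeq table of GRCm38.p6, which served for names and positions only. The array annotation in the headers is on build mm9. Of 55681 probes, 29123 carried a RefSeq accession. Of these, 27656 probes were named by 1 symbol and 1467 were not matched to exactly 1 symbol. The named probes covered 20972 genes, 5554 of them with several probes, and the 28025 unnamed probes were kept as features of their own, which gave 48997 features.

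Values were log2 intensities minus the 75th percentile of each array. Spots of 1 probe were averaged, control spots and outlier spots were left out, and the brightest probe stood for its gene. A feature entered a comparison when it was well above background, by the Feature Extraction call, on at least 50% of the arrays of 1 of the groups compared. Where a gene was not well above background on any array of the dimmer group, its fold is given as "at least": the mean of the brighter group over that of the dimmer group with each dim value raised to the lowest signal well above background on its array. Where it was so on part of a group, the number of arrays is given. For pairs of arrays, list medians were also taken with dim values raised in this way. The number of arrays limits the precision of every value.

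Tests were run with limma 3.58.1 in R 4.3.3, with figures and tables made in Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The tested comparisons were the 6 KO arrays of single mice at 9-12 months against the WT array of their slide, MDS/MPN against MDS, and the KO effect at 9-12 months minus that at 3 months. In the first and the last, groups of 1 array were assumed to vary as the 6 KO arrays do. The disease comparison took its spread from the 5 MDS and MDS/MPN arrays. Its fit held the undetermined array and the WT array of slide 2 as groups of their own, which add no spread, and left out the mixed array. Comparisons of 1 array with 1 array had no replicates and are given as values, beside limma with the spread of the 6 KO arrays, with counts of features at least 2-fold apart set beside those of the 15 pairs among the 6 KO arrays.

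The gene lists were fixed before the data were examined: PRC2 subunits, PRC1 subunits, H3K27 demethylases and trithorax genes, developmental transcription factors, Hoxa and Hoxb genes, Hoxc and Hoxd genes, fetal stem cell genes, CDK inhibitors, myeloid oncogenes, stem cell genes, lymphoid priming genes, B cell markers, T cell markers, NK cell markers, neutrophil granule genes, monocyte, macrophage and dendritic markers, erythroid genes, megakaryocyte and platelet genes, mast cell and basophil genes, eosinophil genes, stromal and endothelial markers, mitosis genes, DNA replication genes, interferon response genes, inflammatory cytokine and NF-kB genes, immediate early genes, p53 target genes, MHC class II genes, histone genes of the replication type, ribosomal protein genes, mitochondrial respiration genes, glycolysis genes, TGF-beta and BMP response genes, and Y-linked genes with Xist. These 34 lists were tested with camera at a preset correlation of 0.01, with the estimated correlation and fry beside it, where at least 3 members were measured. Camera tests whether the members differ from the other genes in 1 direction. For pairs of arrays, the median of each list was set against 10000 random lists matched on mean signal in 20 bins. Such random lists take in neither the spread between arrays nor the correlation within a list. Smaller lists of late and early erythroid and neutrophil genes were written before their test in the closing section.

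Genes were named by a rule fixed with the lists: the PRC2 subunits, then up to 12 genes per direction with the largest change among those past the threshold whose groups did not overlap, then the next by p where fewer passed. From each list came the up to 4 members with the largest change among those past the threshold, or the 2 largest where none passed. For pairs of arrays, the 12 largest differences per direction among genes well above background on both arrays were taken.

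The alternatives were normexp background correction with an offset of 50 and quantile normalization, run on the median spot signal because the mean was absent, quantile normalization alone, the deposited value table under its own labels, no filter or a filter on every array, the median probe, eBayes with trend and robust settings, a 2-fold minimum, each array left out in turn, the mixed array added, the disease groups fitted separately, and each KO array in the place of the WT array. Those chosen after the data were seen used every KO array against both WT arrays with the slide as a block, both WT arrays as 1 group, or the first line of slide 2 alone. The last of these set the MDS arrays against the WT array and left out the mixed array. The mixed array and the WT arrays were also tested as pairs with the spread of the 6 KO arrays. The tests were checked on simulated data with 200 changed features. At the spread of the 6 KO arrays, limma called 62.1% of changes of 4 on the log2 scale in the comparison with WT and 0% in the disease comparison and in the difference of effects. At 0.25 of that spread it called 100%, 100% and 97%. Outlying arrays were looked for among the 6 KO arrays by the gap of an array to its nearest neighbour over the range, with a critical value of 0.625.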

Results

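Gene expression was measured in LSK cells (Lineage-negative, Sca-1-positive, c-Kit-positive), a bone marrow gate that holds blood stem cells and early progenitors, sorted for the donor marker CD45.2 from transplanted C57BL/6 mice. Donor cells carried a tamoxifen-inducible Cre alone (Cre-ERt, WT) or the Cre with floxed Ezh2 (KO), so that tamoxifen deletes Ezh2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2). The 10 arrays comprised 1 WT and 1 KO array labelled 3 months after transplantation and tamoxifen, and 1 WT and 7 KO arrays labelled 9-12 months. Of the 7, 2 came from mice with myelodysplastic syndrome (MDS), 3 from mice with an overlap of MDS and myeloproliferative neoplasm (MDS/MPN), 1 from a mouse with undetermined disease and 1 from a mixed sample of several diseases. Within MDS/MPN, the disease label of replicate 1 adds TC, whose meaning is not given in the sources used here, and the source label of replicate 3 adds CMMoL; the 3 were taken as 1 group. The series description gives n=3 at 3 months, where there is 1 array per genotype, and whether the WT, 3-month KO and mixed arrays hold pooled mice is not given in the sources used here. Each array had 55681 probes, of which 32.5% to 47.5% were well above background, the 75th percentile signal was 78.7 to 301.7 intensity units, and 0 probes were saturated.

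Slide 1 held the WT and KO arrays whose scanner files are labelled 3 months, and slide 2 held the other 8. In the deposited value table the time labels of 4 arrays were exchanged. The columns labelled 9-12 months for WT and mixed KO held the values of the slide 1 scanner files, and the columns labelled 3 months held those of the WT and mixed KO files of slide 2. The SD of the log2 ratio was 0.0002 to 0.0004 between each column and its matching file and at least 0.248 against any other file. The genotype labels were the same in both. Times below are those of the scanner files, each pair is also named by its slide, and statements about either time, those on KO against WT at 9-12 months included, depend on these labels.

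**Figure D1:**
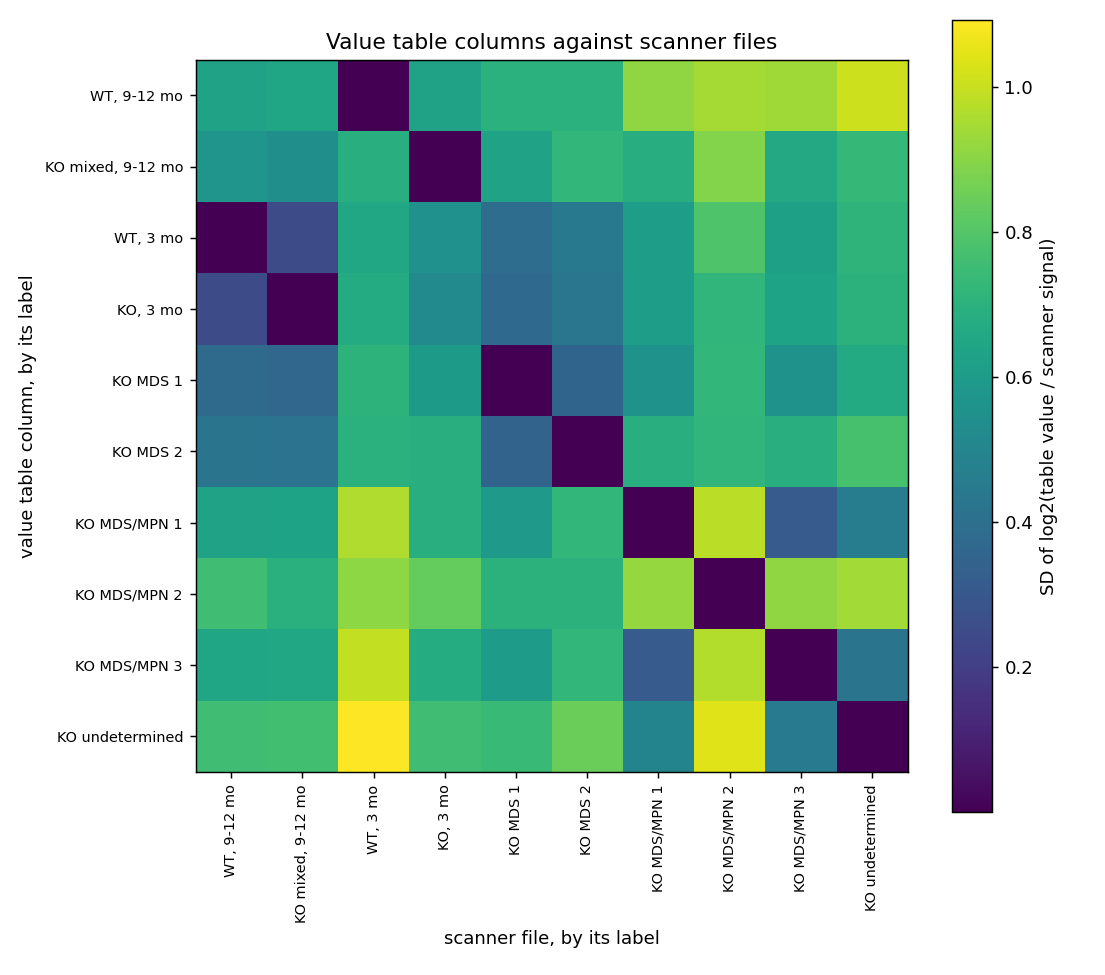
Each cell shows the SD over probes of log2(table value / scanner signal) between a column of the value table (vertical, by its label) and a scanner file (horizontal, by its label), with dark cells for a match. The 6 KO arrays of single mice match the files of the same label, and the WT and KO columns of each time match the files of the other time.

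Ezh2 RNA (chromosome 6, 47530274 to 47595270, GRCm38.p6) showed no difference between the genotypes that passed its test. Its single probe read 2.63 (log2 signal over the 75th percentile) on the WT array of slide 2 and 2.14 to 3.35 on the 6 KO arrays of single mice at 9-12 months, a KO minus WT difference of -0.15 ± 0.52 (SE, 6 KO arrays and 1 WT array, limma adjusted p = 0.9999). On slide 1 the KO array was 0.57 above the WT array, and under the labels of the value table the difference at 9-12 months was 0.35. Neither the exons deleted nor the place of the probe in the transcript is given in the sources used here, so whether the probe reads the deleted part cannot be told, and these values neither show nor exclude a deletion. The other 10 PRC2 subunits ranged from -1.16 for Phf1 (well above background on 3 of 6 KO arrays) to 0.70 for Phf19, and none passed the test.

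In the 6 KO arrays at 9-12 months, genes of mature blood lineages were higher than on the WT array of the same slide, and immediate early and stem cell genes were lower. The erythroid list rose by a mean of 2.38 (log2) over 21 genes, 20 of them with a positive value, in 5 of 6 arrays (adjusted p = 3.39e-09). The call did not hold with the correlation estimated from the data (adjusted p = 0.492 with an estimated correlation). The alpha-globin genes Hba-a1 and Hba-a2 were 46.4-fold and 46.3-fold above WT. The mast cell and basophil list rose by 2.49 over 11 genes, all positive, in 6 of 6 arrays (adjusted p = 3.39e-09), with adjusted p = 0.241 with an estimated correlation. Il1rl1, the receptor for interleukin 33, was at least 18.3-fold and Cma1, a mast cell chymase, at least 8.43-fold above WT. The Il1rl1 probe used gave 4.62 (log2) above WT. Its other probes gave 1.75 and 1.61 and were well above background on 5 and 1 of the 10 arrays.

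The neutrophil granule list rose by 1.67 over 20 genes, 16 positive (adjusted p = 1.03e-07), with adjusted p = 0.202 with an estimated correlation. Lcn2, an iron-sequestering granule protein, stood 4.47 ± 0.86 above WT (adjusted p = 0.0768) and S100a8, a subunit of calprotectin, 3.53 ± 1.39 (adjusted p = 0.855). Monocyte, macrophage and dendritic markers rose by 0.97 over 20 genes, 15 positive (adjusted p = 2.69e-05), with adjusted p = 0.287 with an estimated correlation. The adhesion molecule Vcam1 was at least 6.25-fold and Cd14, a co-receptor for lipopolysaccharide, at least 3.38-fold above WT. Both lists were higher in 6 of 6 arrays. The sort excludes cells with mature lineage markers, and many of these genes are also expressed in progenitors.

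B cell markers rose by 1.80 over 10 genes (adjusted p = 0.00384), with adjusted p = 0.202 with an estimated correlation, and Pou2af1, a B cell coactivator, was at least 3.11-fold and Fcmr, an IgM receptor, at least 4.81-fold above WT, each well above background on 5 of 6 KO arrays. Among features well above background on every array the B cell mean was 0.09 with its direction turned (adjusted p = 0.727), and the calls for T cell markers (mean 0.33, adjusted p = 0.428) and respiration genes (0.31, adjusted p = 0.0546) ended. T cell markers rose by 0.61 over 12 genes (adjusted p = 0.0453, and adjusted p = 0.453 with an estimated correlation). MHC class II genes rose by 0.87 over 10 genes (adjusted p = 0.0453, and adjusted p = 0.784 with an estimated correlation), with Cd74, the invariant chain, 3.22 ± 0.93 above WT. The p53 target list rose by 0.57 over 18 genes (adjusted p = 0.00609), with adjusted p = 0.202 with an estimated correlation. Its most changed members were Pmaip1, which encodes the BH3 protein Noxa, at least 5.01-fold above WT, and Perp, 1.85 ± 0.81. Mitochondrial respiration genes rose by 0.31 over 28 genes (adjusted p = 0.0380, and adjusted p = 0.784 with an estimated correlation).

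Immediate early genes, which respond to growth factors, stress and cell handling, fell by a mean of 2.23 over 15 genes with 0 positive (adjusted p = 0.000125), with adjusted p = 0.784 with an estimated correlation. Fos was -4.77 ± 2.26 and Dusp1, a phosphatase of MAP kinases, -3.90 ± 1.51. The list mean was below WT in 5 of 6 arrays and above it in KO_aged_MDSMPN replicate 2. Stem cell genes fell by a mean of 0.77 over 23 genes, 4 of them positive (adjusted p = 0.0370), with adjusted p = 0.784 with an estimated correlation. Clec1a, well above background on 2 of 6 KO arrays, was -2.42 ± 1.27 and Esam, an endothelial and stem cell adhesion molecule, -2.23 ± 1.03, and the list mean was below WT in 4 of 6 arrays, the MDS arrays being the exceptions.

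**Figure D2:**
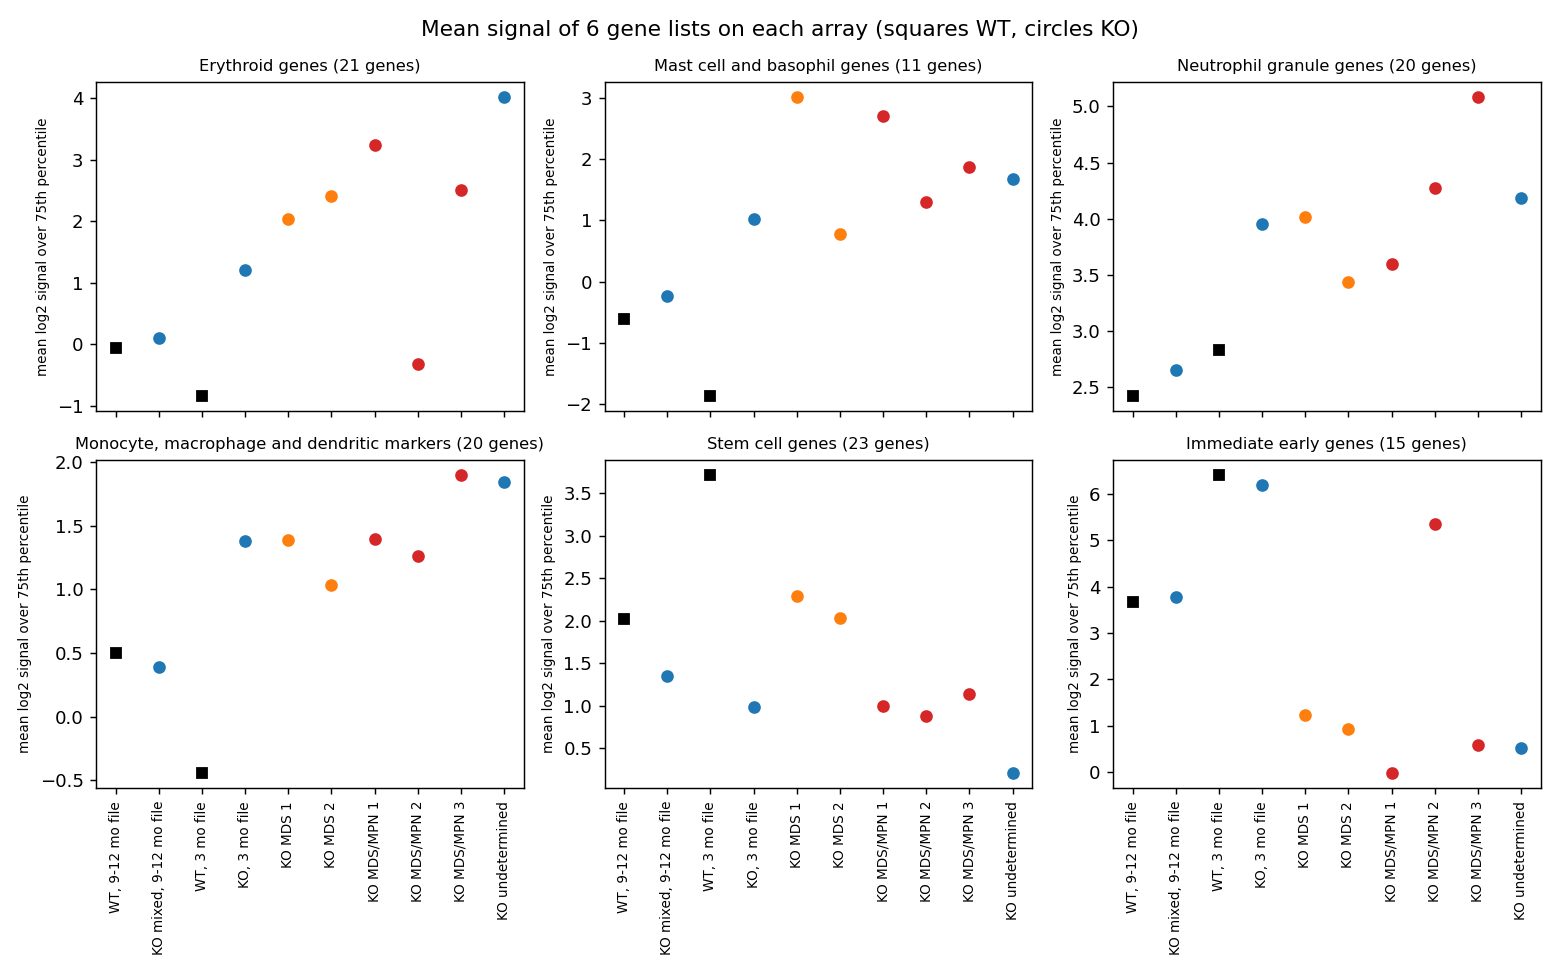
The mean log2 signal over the 75th percentile of 6 gene lists is drawn for each array, with squares for WT, circles for KO, orange for MDS and red for MDS/MPN. The 6 KO arrays of single mice lie above both WT arrays for mast cell, neutrophil and monocyte genes, and KO_aged_MDSMPN replicate 2 stands apart with an immediate early mean of 5.36 against -0.03 to 1.22 on the other 5.

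Of the 33 lists with at least 3 measured members, 11 were called, 9 up and 2 down. Here and in every other comparison, no list call held with an estimated correlation, and fry called 0 lists. Adjusted over all genes, 0 members of any list passed. Adjusted over the list alone, 3 mast cell genes and 1 neutrophil gene were higher, and 1 Hoxa or Hoxb gene was higher and 1 lower. The other 22 lists did not pass, with adjusted p from 0.104 to 0.813. Lineage and stem cell lists among them had means of 0.63 for eosinophil genes, 0.44 for lymphoid priming, 0.24 for NK cell, 0.04 for megakaryocyte and platelet, 0.10 for fetal stem cell and -0.30 for stromal and endothelial genes. Chromatin and developmental lists had means of -0.05 for PRC2 subunits, 0.05 for PRC1 subunits, 0.24 for H3K27 demethylases and trithorax genes, -0.62 for developmental transcription factors and -0.58 for Hoxa and Hoxb genes. Only 4 of 46 developmental transcription factors on the array were measured, with a median of -0.34, and 11 of 21 Hoxa and Hoxb genes. The developmental mean is thus not a result for the whole list. Cell cycle lists had means of 0.23 for mitosis, 0.24 for DNA replication, -0.36 for histone genes of the replication type and -0.12 for CDK inhibitors. The remaining means were 0.18 for myeloid oncogenes, -0.34 for interferon response, -0.22 for inflammatory cytokine and NF-kB genes, 0.06 for ribosomal proteins, 0.11 for glycolysis, 0.70 for TGF-beta and BMP response and -1.72 for Y-linked genes. The last mean is that of Ddx3y, Eif2s3y and Uty, since Xist did not pass the filter on signal above background. The median had the opposite sign to the mean for myeloid oncogenes (-0.18), lymphoid priming (-0.10), NK cell (-0.17) and inflammatory genes (0.42), and camera pointed up for PRC2 and inflammatory genes. Fewer than 3 Hoxc and Hoxd genes were measured, so that list was not tested.

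Leaving out 1 KO array ended 4 of the calls. Stem cell genes were at -0.71 without MDS/MPN replicate 1 (adjusted p = 0.0582), -0.69 without replicate 2 (0.0787) and -0.56 without the undetermined array (0.160). T cell markers were at 0.51, 0.47 and 0.51 without MDS/MPN replicates 1, 2 and 3 (adjusted p = 0.0742, 0.175 and 0.0598). MHC class II genes stayed at 0.72 and 0.96 without MDS/MPN replicates 1 and 2 (0.0742 and 0.0959). Respiration genes shrank from 0.31 to 0.20 without MDS/MPN replicate 1 or 3 and to 0.16 without the undetermined array (0.120, 0.0887 and 0.156). With the 2 MDS arrays alone, which share the first line of slide 2 with the WT array, the mean of stem cell genes was 0.14. That of respiration genes was -0.12, and T cell markers (0.43) and MHC class II genes (0.47) were not called. The mixed array, also in that line, was left out of this fit. Normexp with quantile normalization ended 3 of the 11 calls, those of stem cell genes (mean -0.53, adjusted p = 0.0967), T cell markers (0.24, 0.117) and respiration genes (0.12, 0.0878). Quantile normalization alone ended the same 3 (means -0.83, 0.63 and 0.12, adjusted p = 0.146, 0.0723 and 0.116) and that of MHC class II genes (0.79, 0.0983). Adding the mixed array ended the calls of T cell markers (0.48, 0.0616) and MHC class II genes (0.66, 0.310). The median probe ended that of T cell markers (0.49, 0.0686).

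Hoxa and Hoxb genes, not called with all 6 KO arrays, were called lower without MDS replicate 1 (mean -0.69, adjusted p = 0.0488) and without MDS/MPN replicate 1 (-0.83, 0.0389), 2 (-1.04, 0.00443) or 3 (-0.73, 0.0390). They were also called lower with the mixed array added (-0.84, 0.0163), with both WT arrays as 1 group (-1.31, 0.00125), with every KO array against both WT arrays (-1.27, 5.66e-06) and under the labels of the value table (-2.28, 6.34e-05). Other lists gained a call when 1 array was left out: mitosis (0.34) and DNA replication genes (0.34) without MDS replicate 2, and interferon response (-0.47) and ribosomal protein genes (0.27) without MDS/MPN replicate 2. So did TGF-beta and BMP genes without MDS/MPN replicate 3 (0.71) or the undetermined array (0.81), and eosinophil genes (0.94) without the undetermined array. Under the labels of the value table, mitosis (1.33), DNA replication (0.74) and lymphoid priming genes (1.065) also gained a call as higher, and TGF-beta and BMP genes (-1.50) as lower.

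Of 19589 features, limma called 1 higher and 113 lower between the 6 KO arrays and the WT array. Under the labels of the value table, which put the WT array of slide 1 in this comparison, it called 37 higher and 85 lower with 1 feature shared, and 4 of the 11 list calls were lost, those of B cell markers, T cell markers, p53 targets and respiration genes (means 1.70, 0.57, 0.06 and 0.30, adjusted p = 0.103, 0.103, 0.240 and 0.130). The rise was in Tstd3 (chromosome 4, 21757382 to 21767211, GRCm38.p6), a gene of the thiosulfate sulfurtransferase family, with 2.91 ± 0.46 (adjusted p = 0.0388), at least 6.30-fold in 6 of 6 arrays, and on slide 1 its KO array was 2.85 above WT. Among the falls with the largest values were Cntn5, a neural adhesion molecule, at least 12.8-fold lower (adjusted p = 0.0275), Ncan, a brain proteoglycan, at least 7.20-fold, Lrat, which esterifies retinol, at least 7.55-fold, Uox, urate oxidase, at least 8.25-fold, and Rhox2h, a reproductive homeobox gene, at least 13.1-fold (adjusted p = 0.0431). Ttll13, Pou3f2, Col6a5, Bsnd, Spx, Ccdc78 and Serpina9 were lower by at least 6.06-fold to 11.9-fold. Of the 113 falls, 105 were in features that were well above background on the WT array and on no other array of slide 2. The spread of each feature in this test came from the 6 KO arrays alone. For these 105 features it was thus the spread of background signal over the 75th percentile, not of measured expression. Their adjusted p values, those of Cntn5 and Rhox2h included, therefore do not take in how expression varies between mice. The next rises by p did not pass: Spib, a transcription factor of B and dendritic cells (at least 5.31-fold, adjusted p = 0.0587), Lcn2 (4.47, adjusted p = 0.0768), Batf3, a dendritic cell factor (at least 2.41-fold), Arhgap22, Mapk13, Xdh, Fancg, Rnd3, Csprs, Plbd1 and Cd83, with adjusted p up to 0.132.

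The count rested on single arrays: limma called 0 without KO_aged_MDS replicate 1 (235 up and 629 down at an unadjusted p under 0.05), 0 without KO_aged_MDSMPN replicate 3 (233 up and 567 down), 4 without KO_aged_MDS replicate 2, 12 without the undetermined array and 214 without KO_aged_MDSMPN replicate 2. Limma called 0 features with trend and robust settings (283 up and 560 down at an unadjusted p under 0.05) and 0 among features well above background on every array (133 up and 75 down).

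With every KO array of both slides set against both WT arrays and the slide as a block, a fit chosen after the time labels were seen to conflict, mast cell, erythroid, neutrophil and monocyte genes were the lists with the highest means. Mast cell genes rose by 2.44 over 11 genes, all positive (adjusted p = 7.92e-08, and adjusted p = 0.247 with an estimated correlation). Erythroid genes rose by 2.06 over 21 genes (adjusted p = 1.54e-06, and adjusted p = 0.507 with an estimated correlation), neutrophil granule genes by 1.34 over 20 and monocyte, macrophage and dendritic markers by 1.18 over 18 (adjusted p = 1.23e-05 for both, and adjusted p = 0.247 with an estimated correlation). Stem cell genes fell by a mean of 1.49 over 26 genes, 3 of them positive (adjusted p = 1.54e-09), and Hoxa and Hoxb genes by 1.27 over 14 genes, 2 of them positive (adjusted p = 5.66e-06), both with adjusted p = 0.247 with an estimated correlation. Hoxb5 was -2.71 ± 0.90 and Clec1a -3.50 ± 1.02, well above background on 3 and 2 of the 8 KO arrays and on both WT arrays.

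Genes of the dividing cell rose with them in this fit: mitosis genes by 0.61 over 23 genes, all positive (adjusted p = 1.23e-05, and adjusted p = 0.466 with an estimated correlation), and DNA replication genes by 0.56 over 25, 24 of them positive (adjusted p = 8.01e-06, and adjusted p = 0.549 with an estimated correlation). These rises were largest in the single pair of slide 1, with KO minus WT means of 1.24 for mitosis and 1.13 for DNA replication genes. On slide 2 the 6 KO arrays were 0.23 and 0.24 above WT, not called, and the mixed array 0.38 and 0.22. The slide 1 WT array had the lowest mean of all arrays for both lists (1.65 and 3.61). Plk1, a mitotic kinase, was 1.32 ± 0.55 and Ccne1, the cyclin of the entry into S phase, 2.08 ± 0.86. Smaller rises were called for p53 targets (0.56), T cell markers (0.57), lymphoid priming genes (0.63) and mitochondrial respiration (0.46), and a fall by 1.23 for immediate early genes, with adjusted p = 0.247, 0.247, 0.719, 0.743 and 0.743 with an estimated correlation. B cell markers (0.97, adjusted p = 0.124) and MHC class II genes (0.61, adjusted p = 0.372), called against the WT array of slide 2, were not called in this fit. Of 33 lists 13 were called, 10 up and 3 down. Adjusted over the list alone, 5 mast cell genes, 2 NK cell genes, 1 lymphoid priming gene and 1 p53 target were higher, and 1 NK cell gene and 1 Hoxa or Hoxb gene were lower. Of 22356 features limma called 0 (424 up and 813 down at an unadjusted p under 0.05). The lowest adjusted p was 0.0712, for Tstd3, 2.84 ± 0.34 higher and well above background on 1 of the 2 WT arrays, and Lgr5, a Wnt pathway receptor, at least 2-fold lower.

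The comparison of MDS/MPN with MDS asks how the progenitors differ by disease. In the 3 MDS/MPN arrays mitosis genes rose by a mean of 0.64 over the 2 MDS arrays, with 23 of 23 genes positive (adjusted p = 6.06e-07, and adjusted p = 0.509 with an estimated correlation). Stem cell genes fell by a mean of 1.03 over 24 genes, 6 of them positive (adjusted p = 8.40e-07, and adjusted p = 0.385 with an estimated correlation). Sult1a1, a sulfotransferase well above background on 2 of 3 MDS/MPN arrays, was -5.70 ± 0.85 (adjusted p = 0.939) and Hlf, a transcription factor of long-term stem cells, -2.87 ± 0.54 (adjusted p = 0.973). Mki67, a proliferation antigen, was 1.35 ± 1.19 and Cenpe, a centromere motor protein, 1.34 ± 1.07.

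DNA replication genes rose by 0.37 over 25 genes and mitochondrial respiration genes by 0.47 over 28 (adjusted p = 0.000524 for both), interferon response genes by 0.32 over 26 (adjusted p = 0.00173), MHC class II genes by 0.78 over 10 (adjusted p = 0.00535) and neutrophil granule genes by 0.61 over 21 (adjusted p = 0.0484). Myeloid oncogenes fell by 0.38 over 23 genes (adjusted p = 0.0138). Each of these 6 lists had adjusted p = 0.781 with an estimated correlation. Among the most changed members, Ccne1 was 1.02 ± 0.59, Igtp, an interferon-induced GTPase, 1.42 ± 0.38, H2-Eb1 1.89 ± 0.60, Cebpe, a factor of granulocyte maturation, 1.87 ± 0.70, and Flt3, a receptor of early progenitors, -1.99 ± 0.69. Of 32 lists 8 were called, 6 up and 2 down. Adjusted over the list alone, 6 stem cell genes were lower and 1 inflammatory and 1 TGF-beta or BMP gene were higher.

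No single gene passed in this comparison: of 20724 features limma called 0 (309 up and 613 down at an unadjusted p under 0.05). The next by p among the higher genes were Il1b, the interleukin 1 beta gene, at least 2.42-fold, Pde10a, a phosphodiesterase, at least 3.09-fold, Gdf3 and Id1. The next among the lower genes were Cldn5, a tight junction protein well above background on both MDS arrays and 1 of 3 MDS/MPN arrays, -3.36 ± 0.41, Tsc22d3, a glucocorticoid response gene, -2.73 ± 0.36, Hacd4, Trib3, Garnl3 and Cyp26b1, which degrades retinoic acid, at least 7.29-fold. The MDS arrays lie in the first line of slide 2 and the MDS/MPN arrays in the second, so disease and position cannot be told apart. Without KO_aged_MDSMPN replicate 2 the interferon list was at 0.02 with its direction turned, the neutrophil list was no longer called although its mean stayed at 0.61 (adjusted p = 0.638), and 4088 features were up and 2387 down at an unadjusted p under 0.05, with 0 called. Neutrophil genes were also not called among features well above background on every array (0.60, adjusted p = 0.0859).

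Leaving out another array ended 5 calls of the disease comparison, with adjusted p from 0.0597 to 0.632, and several means shrank. Without MDS replicate 1 myeloid oncogenes were at -0.29. Without MDS replicate 2 neutrophil genes were at 0.29, DNA replication genes at 0.17 and respiration genes at 0.26. Without MDS/MPN replicate 1 myeloid oncogenes were at -0.17, MHC class II genes at 0.59 and respiration genes at 0.24. Without MDS/MPN replicate 3 neutrophil genes were at 0.26, DNA replication genes at 0.29, MHC class II genes at 0.55 and respiration genes at 0.23. Eosinophil genes, at -0.92 and not called with all 5 arrays (adjusted p = 0.0732), were called lower without MDS replicate 2 (-1.80, adjusted p = 2.75e-07), without MDS/MPN replicate 1 (-1.22, 0.00336) or 3 (-1.06, 0.0290), and with no filter (-0.92, 0.000255). Without MDS/MPN replicate 1, erythroid genes were called lower (-1.13, 0.00336). Without MDS/MPN replicate 1 or 3, Hoxc and Hoxd (1.87 and 1.72), inflammatory (0.78 and 0.71) and immediate early genes (1.90 and 1.64) were called higher and ribosomal protein genes lower (-0.32 for both). Without MDS/MPN replicate 2, immediate early (-1.10), Hoxa and Hoxb (-0.94) and lymphoid priming genes (-0.85) were called lower and histone (0.65), glycolysis (0.54) and ribosomal protein genes (0.38) higher. Mast cell genes were called higher without MDS replicate 1 (1.19) and lower without MDS replicate 2 (-1.05).

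**Figure D3:**
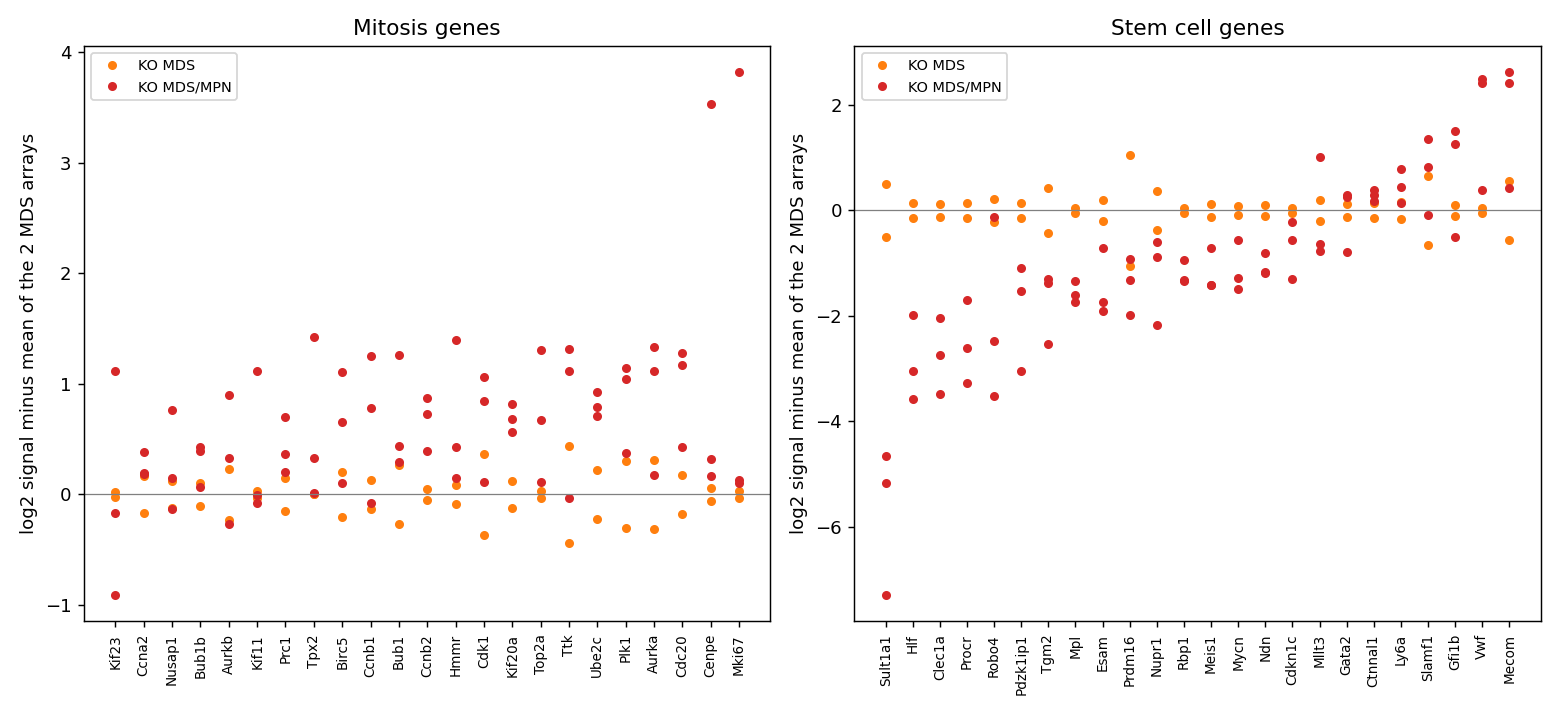
For each mitosis gene (left) and stem cell gene (right), points give the log2 signal of the 2 MDS arrays (orange) and the 3 MDS/MPN arrays (red) minus the mean of the MDS arrays. The mean of MDS/MPN is above MDS for 23 of 23 mitosis genes and for 6 of 24 stem cell genes.

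The pair of slide 1, labelled 3 months in the scanner files and 9-12 months in the value table, shows the KO array apart from WT in lineage and stem cell genes. It had 1 array per genotype and no replicate. Car1, a carbonic anhydrase of red cell precursors, was 51.4-fold higher in KO, Tspo2, an erythroid membrane protein, 31.7-fold, Cx3cr1, the fractalkine receptor of monocytes, 25.8-fold, Ms4a3, a gene of granulocyte and monocyte progenitors, 20-fold, Ly86 19.1-fold, F13a1 18.7-fold and Il1rl1 15.6-fold. Mefv, Slc38a5, Hp, Alox5 and Sphk1 were 17.2-fold to 31.1-fold higher. Sult1a1 was 241-fold lower in KO, Gstm2 114-fold, Nupr1 31.1-fold, Mmrn1, a platelet and endothelial protein, 26.8-fold, and Klrb1c 24.9-fold. Ccn1, Jam2, Pde6h, Matn4, Trpc6, Cavin2 and Slc24a5 were 15.5-fold to 26.4-fold lower.

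By list, 22 of 26 stem cell genes were at least 2-fold lower on the slide 1 KO array (median -2.86) and 10 of 14 Hoxa and Hoxb genes (median -2.28), with Hoxb8 at least 40.3-fold and Hoxb5 at least 12.7-fold lower. Eosinophil genes had a median of -2.48 and TGF-beta and BMP genes of -1.06. Each of these 4 medians lay below those of all 10000 random lists matched on signal. Mast cell genes had a median of 3.38, monocyte genes of 2.39, erythroid genes of 2.16, mitosis genes of 1.36, histone genes of 1.37, DNA replication genes of 1.06 and interferon response genes of 1.04, each above all 10000 random lists. These ranks do not measure the spread between arrays. Among the 6 KO arrays, list means ranged from -0.33 to 4.01 for erythroid, 3.81 to 4.90 for DNA replication and 1.66 to 2.65 for interferon genes. They ranged from 0.78 to 3.01 for mast cell, 1.03 to 1.90 for monocyte and 2.44 to 3.48 for mitosis genes. With genes dim on 1 array set at their bound, the medians were -2.64 for stem cell (21 of 26 at least 2-fold lower), -1.67 for Hoxa and Hoxb, -0.81 for TGF-beta and BMP, 2.85 for mast cell and 1.51 for monocyte genes. Of 22421 features 2872 were at least 2-fold higher and 2722 lower, and among 19199 features well above background on both arrays 3372 (17.6%) were 2-fold apart. The 15 pairs of KO arrays of single mice had 368 to 8207 such features, with a median of 3286, so the difference between the genotypes lay within the range between 2 such KO arrays. With the spread of the 6 KO arrays in place of replicates, limma called 0 features (495 up and 900 down at an unadjusted p under 0.05).

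The mixed KO array of slide 2, labelled 9-12 months in the scanner files and as a 3-month KO in the value table, was close to its WT array. Among 17096 features well above background on both, 362 (2.12%) were at least 2-fold apart, 221 higher and 141 lower, fewer than in any of the 15 pairs of KO arrays. Genes of lymphoid precursors were among the higher ones: Vpreb3 was 15.1-fold, Ly6d 5.70-fold and Vpreb1 5.03-fold above WT, the Vpreb genes being parts or relatives of the surrogate light chain. Rnase2a was 6.31-fold and Ear2, an eosinophil ribonuclease, 6.05-fold higher, and Hmga2, a chromatin protein of fetal stem cells, 5.51-fold. Igfbp7, Zpbp2, Chga, Ddx4, Bex2 and H2bc22 were 4.80-fold to 6.18-fold higher. Lrmda was 9.01-fold lower, Nupr1 4.92-fold and Vwf, von Willebrand factor, 4.84-fold, with Enox1, Pate5, Phyhd1, Sepsecs, Rab20, Gstm2, Mocos, Kifc5b and Zfp597 4.81-fold to 7.08-fold lower. The medians of eosinophil (1.81), B cell (1.81), lymphoid priming (1.21), T cell (0.59), mitosis (0.38) and DNA replication genes (0.20) lay above all 10000 random lists, and those of stem cell (-0.64), megakaryocyte (-0.62) and MHC class II genes (-0.47) below all. Mast cell (-0.12), monocyte (-0.03), neutrophil granule (0.05), erythroid (0.13) and immediate early genes (0.12) had medians within the range of the random lists. The rises and the fall of these lists in the 6 KO arrays were thus not seen in the medians of the mixed array. Among the 6 KO arrays the list means ranged from 2.44 to 3.48 for mitosis and from 3.81 to 4.90 for DNA replication genes. With B cell genes dim on 1 array set at their bound, their median was 0.39. With the spread of the 6 KO arrays in place of replicates, limma called 0 features for the mixed array (384 up and 400 down at an unadjusted p under 0.05).

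Across 14298 features well above background on every array, the KO minus WT differences of slide 1 correlated at r = 0.397 (Spearman 0.376) with those of the 6 KO arrays against the slide 2 WT array, with no array shared. The differences of the mixed array correlated at r = 0.433 with those of the 6 arrays when both used the WT array of slide 2. A shared array alone gave r = 0.656 in simulated data with no effect, but with a covariance of 0.346 against 0.067 in the data. The simulation thus did not match the spread of the mixed pair, and how much of r = 0.433 the shared array gives cannot be told. With the 6 set against the WT array of slide 1, the differences of the mixed array correlated at r = 0.166. These correlations are across features, which are not independent replicates. They were 4 values of 1 family, the fourth being r = 0.189 between the differences of slide 1 and those of the mixed array.

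The difference between the KO effect labelled 9-12 months and that labelled 3 months asks whether deletion acts differently with time. Under the scanner file labels, stem cell genes had a less negative effect at 9-12 months, with a mean difference of 2.003 over 26 genes, 23 positive (adjusted p = 3.04e-08, and adjusted p = 0.450 with an estimated correlation). TGF-beta and BMP response genes rose by 1.92 over 14 genes (adjusted p = 2.88e-06, and adjusted p = 0.0858 with an estimated correlation). Eosinophil genes rose by 2.58 over 9 (adjusted p = 0.000357), Hoxa and Hoxb genes by 1.26 over 16 (adjusted p = 0.00281), CDK inhibitors by 1.69 over 7 and megakaryocyte and platelet genes by 0.92 over 21 (adjusted p = 0.0150 for both), with adjusted p = 0.552, 0.362, 0.362 and 0.772 with an estimated correlation. Among features well above background on every array the mean of Hoxa and Hoxb genes was -0.45 (adjusted p = 0.716) and CDK inhibitors were not called (adjusted p = 0.120).

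Mitosis genes fell by a mean difference of 1.01 over 23 genes and DNA replication genes by 0.89 over 25 (adjusted p = 0.00170 for both), interferon response genes by 1.17 over 27 (adjusted p = 0.00281), histone genes by 1.55 over 11 (adjusted p = 0.0107) and monocyte, macrophage and dendritic markers by 0.85 over 20 (adjusted p = 0.0365). Their values were adjusted p = 0.686, 0.772, 0.686, 0.690 and 0.686 with an estimated correlation. The median over all features was -0.23, against which these means should be set. Isg15, an interferon-induced modifier, was at -3.41 ± 1.47. Adjusted over the list alone, 2 Hoxa or Hoxb genes and 2 TGF-beta or BMP genes were higher. Of 23290 features limma called 0 (556 up and 604 down at an unadjusted p under 0.05), with Acox2 and Lbhd2 among the next by p of the higher and Asb9, Adam32 and Sftpd among those of the lower (adjusted p = 0.417), each well above background on 1 of the 10 arrays. Under the labels of the value table, 10 of the 11 list calls changed direction and the other was lost. The call for monocyte markers ended without KO_aged_MDSMPN replicate 1 (mean -0.84, adjusted p = 0.0653), with normexp and quantile normalization (mean -0.41, adjusted p = 0.0905), with quantile normalization alone (-0.58, 0.0629) and with the median probe (-0.69, 0.102). B cell markers gained a call without MDS replicate 2 (1.29), MDS/MPN replicate 2 (1.11) or 3 (1.28) or the undetermined array (1.27), and with the median probe (1.35). Without MDS/MPN replicate 2, erythroid (0.87) and immediate early genes (-2.60) did so too.

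The WT array of slide 2 differed from that of slide 1 in immediate early, signalling, stem cell, lineage and cell cycle genes. Nr4a1, an orphan nuclear receptor, was 84.3-fold, Fosb 35.0-fold and Atf3 32.3-fold lower on slide 2, as were Id1 (130-fold) and Id3 (42.0-fold), inhibitors of differentiation induced by BMP, and Mt2 (63.7-fold), a metallothionein. Cyp26b1, Sult1a1, Bhlhe40, Ramp2, Gnaz and Rarb were 23.5-fold to 35.9-fold lower. Jaml was 15.5-fold, the histone gene H2ac6 13.4-fold and F13a1 7.21-fold higher on slide 2. Serpina9, Espl1, Sepsecs, Kifc5b, Usp6nl, Mxd3, Cx3cr1, Btbd11 and H3c7 were at least 6.59-fold higher. Immediate early genes had a median of -2.63, inflammatory genes of -2.21, TGF-beta and BMP genes of -2.16 and stem cell genes of -1.20, below all 10000 random lists. So were eosinophil (-1.88), Hoxa and Hoxb (-1.26) and megakaryocyte genes (-0.66). Medians above all were those of monocyte (1.54), histone (1.40), mitosis (0.95) and DNA replication genes (0.65). For all these lists but inflammatory genes (0.50), the median KO minus WT difference on slide 1 had the same direction. With genes dim on 1 array set at their bound, the medians were -1.61 for inflammatory, -0.47 for TGF-beta and BMP, -1.12 for stem cell and -0.75 for Hoxa and Hoxb genes. Of 22038 features 2176 were at least 2-fold higher and 3111 lower, limma with the spread of the 6 KO arrays called 14, and time and slide cannot be told apart.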

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

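The tests in this part were chosen only after the results were seen, except those of late and early erythroid and neutrophil genes in the 6 KO arrays, which were written before. Among the 6 KO arrays of single mice, 74 values were tested for an array far from the others and 8 stood out, where chance gives about 1 in 20. KO_aged_MDSMPN replicate 2 held 7 of them: a 75th percentile signal of 301.7 against 89.4 to 145 on the other 5, a mean of immediate early genes of 5.36 against -0.03 to 1.22, of inflammatory genes of 2.08 against 0.12 to 0.79, of ribosomal protein genes of 9.01 against 9.94 to 10.5, of developmental transcription factors of -2.54 against -1.21 to -0.64, Eif2s3y of -5.90 against -0.79 to 2.24 and Uox of -5.96 against -4.48 to -3.80. Uox was well above background on 0 of the 6 KO arrays, so its values are background signal over the 75th percentile of each array. Its place among the 7 is therefore not independent of the 75th percentile signal. The mean of developmental transcription factors was taken over 4 genes. KO_aged_MDSMPN replicate 1 had a median background of 43 against 28 to 31. The KO effect differed between the times of the scanner file labels for 11 lists, by the camera test of the difference at the preset correlation: 1.26 for Hoxa and Hoxb genes, 1.69 for CDK inhibitors, 2.003 for stem cell genes, 0.92 for megakaryocyte, 2.58 for eosinophil and 1.92 for TGF-beta and BMP genes, and -0.85 for monocyte, -1.01 for mitosis, -0.89 for DNA replication, -1.17 for interferon response and -1.55 for histone genes. All 11 calls were lost with an estimated correlation, and 10 changed direction and 1 was lost under the labels of the value table.

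The 113 features called lower in the 6 KO arrays than on the WT array were mostly bright on that array alone. On the WT array of slide 1, 7.96% of them were well above background (3.71 to 14.58, exact binomial interval, n = 113), as signal present on a single WT array would give. On slide 1 the 11 features that were well above background on at least 1 array had a median KO minus WT of -0.298 (-1.59 to 0.119), too few to decide on lower expression with Ezh2 deletion, which stays open. Setting each of the 7 arrays alone against the other 6 gave as many calls for 4 of the 7, the WT array included, with the most for KO_aged_MDSMPN replicate 2. A count as high as that of the WT array was therefore not particular to it. The 7 splits are too few for a share under 0.05, so the test cannot decide whether the calls arose by chance.

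Erythroid and neutrophil genes were higher in the 6 KO arrays than on the WT array. Against the WT array of slide 1 the smaller of the mean rises was 1.268, for neutrophil genes, with 3.15 for erythroid genes. Slide and labelled time also differ in this comparison, so it cannot decide whether the choice of WT array was the cause. Within slide 2 the mixed KO array was 0.18 (erythroid) and 0.23 (neutrophil) above the WT array. Within slide 1 the KO array was 2.04 and 1.12 above its WT array. Late neutrophil genes rose more than early ones, by 1.877 (0.2 to 2.725, bootstrap over genes; medians 3.03 of 9 and 1.15 of 6, with 6 and 6 well above background on the WT array), so mature neutrophils in the sort may contribute, with mean levels of S100a8 and S100a9 of 4.58 and 5.03, although the Lineage gate would remove them. The pair of slide 1 lacked this pattern: its late neutrophil genes had a median KO minus WT of 0.06 (S100a8 0.22, S100a9 -0.34) and its early ones of 3.45 (Mpo 3.66, Elane 3.46). In the mixed pair the medians were 0.86 and -0.60. For red cells the difference of late and early genes was 0.697 (-1.375 to 3.689; medians 2.87 of 7 and 2.18 of 8, with 4 and 8 well above background on the WT array), so mature red cells and erythroid progenitors cannot be told apart, and on slide 1 the medians were 0.35 and 2.11. A change of the progenitors with Ezh2 deletion stays open for both lineages.

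The time labels of the WT and KO pairs differ between the scanner files and the value table. If the table is right, slide 1 holds the mixed KO sample at 9-12 months, and its difference from WT correlated at r = 0.3966 with that of the 6 KO arrays with no array shared, although an effect of genotype at 3 months could give a correlation too. If the files are right, the slide 2 pair holds the mixed sample, which lay closer to WT (SD of log2 differences 0.311) than any of 57 averages of the 6 mice, of which 0 were as close and the lowest was 0.451. The makeup of the mixed sample is not given in the sources used here and the averages are an assumed profile, so the labels of the scanner files stay open.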

How the results depend on the processing

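The alternatives with both WT arrays as 1 group, every KO array with the slide as block, or the first line of slide 2 alone, and limma on the mixed pair and the WT pair, were chosen only after the results were seen. Of the named genes' values under the alternatives 1278 kept direction and side of the threshold, and 133 lost and 17 gained a call. Another 68 changed direction with no call in either fit. Of the list values 1329 kept both, and 110 lost and 72 gained a call. Another 134 changed direction with no call in either fit, and 20 reversed, with a call in at least 1 of the fits. For KO against WT at 9-12 months, where 114 features were called, limma called 246 with quantile normalization, 50 with no filter (48978 features tested), 180 with the mixed array added, and 0 to 214 leaving out 1 array. It called 0 among features well above background on every array (133 up and 75 down at an unadjusted p under 0.05), 0 with trend and robust settings (283 and 560), 0 with disease groups fitted separately (355 and 670), 0 with both WT arrays as 1 group (1013 and 1198), 0 with every KO array and the slide as block (424 and 813) and 0 with the first line of slide 2 alone (715 and 908). In the place of the WT array, KO_aged_MDS replicate 2 gave 42, KO_aged_MDSMPN replicates 1 and 2 gave 204 and 969, and the undetermined array 394. The 11 list calls became 7 with quantile normalization alone and 8 with normexp followed by quantile normalization, which is called normexp in the rest of this section. The calls of all 3 tested comparisons became 0 with an estimated correlation and 0 with fry. List means that reversed were TGF-beta and BMP genes at -1.50 with the value table under its labels, B cell markers by their test at 0.0905 on features well above background on every array, and stem cell genes at 0.14 and respiration genes at -0.12 with the first line of slide 2 alone. Between MDS/MPN and MDS, mast cell genes reversed to -1.05 without KO_aged_MDS replicate 2 (range leaving out 1 array -1.05 to 1.19), and without KO_aged_MDSMPN replicate 2 immediate early genes reversed to -1.10 (range -1.10 to 1.90), ribosomal protein genes to 0.38 (-0.32 to 0.38) and interferon genes, by their test, at 0.0167 (0.0167 to 0.53). For the difference of KO effects limma called 184 features with quantile normalization and 2 with the value table. There the exchanged labels set the other pair against the 6 arrays, and the list means became -1.85 for Hoxa and Hoxb, -1.30 for CDK inhibitors, -1.69 for stem cell, 2.03 for monocyte, -0.28 for megakaryocyte, 3.38 for mast cell, -2.29 for eosinophil, 0.96 for mitosis, 0.52 for DNA replication, 0.63 for histone and -1.58 for TGF-beta and BMP genes. Hoxa and Hoxb genes were at -0.45 on features well above background on every array. Features 2-fold apart in the slide 1 pair, 5594, became 1398 with normexp, 1737 with the table's labels, 3372 with both arrays well above background and 9047 with no filter, and limma with the spread of the 6 KO arrays called 0 (495 up and 900 down at an unadjusted p under 0.05). Between the WT arrays 5287 became 1459 with normexp, 2455 with both well above background and 12629 with no filter, and for the mixed array 1735 became 535, 362 and 5103, and 5615 with the table's labels. Limma with the spread of the 6 KO arrays called 14 between the WT arrays and 0 for the mixed array (384 up and 400 down at an unadjusted p under 0.05). Ezh2 under the table's labels was 0.35 at 9-12 months and -0.004 at 3 months. Where the exchanged labels or the arrays left out do not show it, the cause was not tested. Normexp used the median spot signal because the mean was absent. No paired analysis was run because the labels carry no replicate numbers shared between groups. The titles of the single mice share prefixes between disease groups, but their meaning is not given in the sources used here and they were not used. Only the slide served as a block, for every KO array against both WT arrays as given above. Signal over background limits the dim genes, since 32.5% to 47.5% of probes were well above background.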

Other observations

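All values of this part were looked at only after the results were seen. Xist was well above background on KO_aged_MDSMPN replicate 2 (2.09) and on the undetermined array (1.22) and on none of the other 8. Ddx3y was not well above background on those arrays (-5.74 and -4.23) and was on the other 8. Y-linked Eif2s3y was well above background on the undetermined array (-0.79) and not on KO_aged_MDSMPN replicate 2 (-5.90). KO_aged_MDSMPN replicate 2 had 2496 features well above background on it alone among the arrays of slide 2, against 258 to 488 on the other 7. The undetermined array had an erythroid mean of 4.01 and a stem cell mean of 0.20, the highest and the lowest of the 10 arrays.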
